A study of Mus musculus with 435 samples.

How the data were processed

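Livers of 435 leptin receptor deficient (db/db) F2 mice were profiled on Affymetrix arrays, with 1 array per mouse. Per the labels, DBA/2J females were crossed to C57BL/6 males that carried a copy of the db mutation, the F1 carriers were interbred, and the db/db offspring ate chow until 5 or 12 weeks of age. Liver pieces were snap frozen and total RNA was extracted with Trizol, per the labels' protocols. Age and sex were taken from the labels and gave 118 females and 101 males at 5 weeks, and 110 females and 106 males at 12 weeks. Litters were not given in the sources used here, so mice were treated as independent. The labels also give each mouse's plasma, weight and fat measurements. The unit of the whole-body fat and lean values from nuclear magnetic resonance (NMR) is not given in the sources used here.

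The deposited table holds log2 expression values that the authors made with RMA, a method that corrects background, normalizes arrays to each other and summarizes probes into probe sets, per the submitters' processing notes. The RMA version, and whether the 435 arrays were normalized in a single run, are not given in the sources used here. The deposited values covered 15397 probe sets and 0 missing values. Array medians lay between 5.56 and 5.70. No pair of arrays was identical: pairwise correlations lay between 0.9725 and 0.9955, with a median of 0.9892. Of the probe sets, 13516 had 1 gene symbol, 162 had several and 1719 had none given. For 13428 of them the Entrez ID was found in the RefSeq gene table of GRCm38.p6, which changed 0 symbols. Probe sets with 1 symbol were kept, and for the 134 genes with more than 1 the probe set of the highest mean was used, which left 13379 genes. The SD of a probe set over all arrays had a median of 0.18 and a highest value of 0.93. Many genes that vary strongly in mouse liver are absent from the table used here and were not analysed here. Detection calls were not used here, so the number of arrays limits the precision and signal over background is unknown.

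The array names in the labels hold a 6-value batch code and 25 plate codes, whose meaning is not given in the sources used here. Batches 1 to 4 held 99, 138, 110 and 86 arrays of all 4 groups, and batches 5 and 6 held a single 12-week female each. Over all genes, the first principal component carried 10.6% of the variance, of which 85.4% lay between groups and 10.7% between batches. Batch was a covariate in the fits of expression. Gene calls, differences of traits between groups and correlations between traits were recomputed within each of the 4 large batches. The shares of calls with the same sign in a batch alone are of calls from all mice. Those mice include the batch itself, so such agreement is partly built in and is not an independent replication. Of the gene lists, only the matrix list was recomputed within batches, for the age difference.

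Expression was tested with limma (lmFit and eBayes) on the deposited log2 values. A single fit with group and batch gave 12 against 5 weeks in each sex, males against females at each age, and the difference between the age effects of males and females (the age by sex interaction). A slope is the log2 change per 1 SD of a trait within an age, with sex and batch as covariates. Glucose, insulin, triglycerides, total cholesterol and the liver fat fraction were put on the log2 scale, body fat percent was not, and each was scaled within sex. Differences of the glucose slope between the sexes at 12 weeks and between ages were tested as interaction terms. P-values were adjusted by Benjamini-Hochberg over the 13379 genes and a gene was called at an adjusted p under 0.05. Values given as ± are standard errors (SE) for expression and SD for traits.

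A set of 32 gene lists was fixed before the data were examined. They cover sterol synthesis, fatty acid synthesis, fatty acid oxidation, gluconeogenesis and other insulin-repressed genes, glycolysis, lipid droplets and steatosis, bile acid and sterol transport, male-biased and female-biased liver genes, sex chromosome genes, cell cycle, immature liver genes, unfolded protein response, acute phase, interferon-stimulated genes, extracellular matrix, circadian clock, oxidative phosphorylation, xenobiotic metabolism, heat shock proteins and immediate early genes. Markers of acinar cells, adipocytes, erythroid cells, macrophages, lymphocytes, neutrophils, endothelial cells, stellate cells, cholangiocytes, skeletal muscle and hepatocytes complete the set. Coverage was partial, for example 17 of 25 sterol synthesis genes, 16 of 25 matrix genes, 12 of 34 cell cycle genes and 7 of 26 male-biased genes; 9 members were found only under an older symbol. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. Camera compares the list with all other genes, and the adjusted p given with a list mean is camera's. Where members of a list are counted, those not given as going either way were not called. Of 201 list calls over the 19 comparisons, 62 held with a correlation estimated per list.

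The rule for named genes was also fixed before the data were examined. It takes, for the age, sex and interaction comparisons and the 12-week glucose and insulin slopes, the 10 largest positive and 10 largest negative coefficients among called genes with the same sign in each of the 4 large batches, and 5 and 5 for every other slope. It adds up to 4 members with the smallest p of a list that is discussed, and the sex chromosome genes.

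Traits were compared between groups by two-sided permutation tests with 100000 resamples (smallest p 1e-05), on the log2 scale except for body fat percent and mesenteric fat. The 74 tests of 20 traits were adjusted together. Correlations between traits within a group were tested the same way, as a family of 44. Added after seeing the data were a test of the age by sex difference for 18 traits and 4 tests, adjusted together, of the 12-week mice against their own glucose and insulin at 5 weeks, with the sign of each mouse's difference permuted.

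On simulated changes of 0.1, 0.2, 0.3 and 0.5 (log2) in 50 genes each, the age comparison in females recovered 78, 98, 100 and 100% of the changed genes, and the interaction 26, 84, 96 and 100%. Changes of 0.05, 0.1, 0.2 and 0.3 per SD were recovered in 66, 98, 100 and 100% of genes for the 12-week glucose slope. Its age difference gave 36, 88, 100 and 100%. With 1 list shifted camera called 0 others, which does not bound false calls in correlated lists.

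Alternatives set before the data were examined were no batch term, plate in place of batch, quantile normalization, median centring, leaving out the dimmest 40% of genes, all probe sets, the mean of a gene's probe sets, eBayes with trend and robust, each large batch left out, arrays that go against their sex label left out, unlogged traits, normal scores, body weight, insulin or glucose as covariates, each sex alone, an estimated correlation, rank-based camera and rank tests of traits. Slope differences between ages for the 5 traits other than glucose were added after seeing the data, as were these differences per log2 unit of a trait (per percent point for body fat) in place of 1 SD and the shuffles of traits. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), mclust 6.1.1, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Probe sets with several or no symbols were left out of all but 1 alternative, because their gene is not settled.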

Results

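Liver expression of 13379 genes was compared across 435 db/db F2 mice, which lack a working leptin receptor and become obese and diabetic on chow. The groups were 118 females and 101 males at 5 weeks and 110 females and 106 males at 12 weeks, with 1 array per mouse. The comparisons addressed how the liver differed between ages and sexes, and how expression varied with glucose, insulin, lipids and fat. The X-linked genes Eif2s3x, Kdm5c, Kdm6a and Ddx3x served as a check of the sex labels: in 8 arrays Eif2s3x and the mean of the other 3 genes both lay nearer to the other sex, and these were kept under their labels. Eif2s3x placed the same 8 there and the mean of the other 3 genes 74.

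Plasma glucose was higher at 12 than at 5 weeks in both sexes and reached its highest level in males. It averaged 264 ± 106 mg/dl in females and 266 ± 106 in males at 5 weeks, and 455 ± 159 and 575 ± 147 mg/dl at 12 weeks (SD). The ratio of geometric means between ages was 1.71 in females and 2.20 in males, and males exceeded females 1.30-fold at 12 weeks (permutation test, adjusted p = 1.9e-05 for each). Males and females did not differ detectably at 5 weeks (adjusted p = 0.792). Insulin was 52.7 ± 23.0 uIU/ml in females and 50.9 ± 26.5 in males at 5 weeks, and 130.1 ± 71.7 and 72.3 ± 52.4 uIU/ml at 12 weeks. The ratio between ages was 2.17 in females (adjusted p = 1.9e-05) and 1.18 in males, which did not pass on the log2 scale (adjusted p = 0.122) but did without the log (adjusted p = 0.000546) and by ranks (adjusted p = 0.0448). The 12-week mice had also been measured at 5 weeks. Within mice glucose rose 2.02-fold in females (higher in 101 of 105) and 2.39-fold in males (102 of 104), and insulin 2.50-fold in females (95 of 110, permutation test, adjusted p = 1.33e-05 for each). Male insulin passed as well, at 1.30-fold (63 of 106, adjusted p = 0.00084), with log2 values of 0.38, 0.30, 0.90 and 0.042 in batches 1 to 4. The lowest batch values of the other 3 were 0.80, 1.17 and 0.82. At 12 weeks male insulin was 0.511 times the female level (adjusted p = 1.9e-05). Within batches 1 to 4, the male minus female log2 difference of insulin at 12 weeks was -1.36, -1.10, -0.084 and -1.28, and that of glucose 0.69, 0.31, 0.16 and 0.58.

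Body weight went from 24.9 ± 4.31 to 51.9 ± 4.99 g in females and from 26.3 ± 4.19 to 52.1 ± 5.45 g in males. Body fat went from 36.2 ± 4.16 to 54.7 ± 4.52% in females and from 33.7 ± 3.21 to 53.0 ± 3.95% in males. The liver fat fraction by NMR rose from 0.158 ± 0.0200 to 0.209 ± 0.0370 in females and from 0.153 ± 0.0220 to 0.222 ± 0.0461 in males. Triglycerides rose 1.31-fold in females, to 135 ± 96.9 mg/dl (adjusted p = 0.000828), and 1.49-fold in males, to 209.9 ± 151 mg/dl. Free fatty acids rose 1.40-fold in females and 1.41-fold in males. Total cholesterol rose 1.31-fold and 1.22-fold. Except where a p is given, these age differences had an adjusted p of 1.9e-05 by permutation test. Unesterified cholesterol did not differ detectably (adjusted p = 0.197 and 0.683). Within batches 1 to 4 the log2 age difference of the liver fat fraction was 0.54, 0.47, 0.29 and 0.35 in females and 0.51, 0.57, 0.58 and 0.46 in males. That of triglycerides in females was 0.49, 0.64, 0.50 and -0.32, with batch 4 the other way.

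The age differences themselves differed between the sexes for 8 of 18 traits. The gonadal depot grew 6.08-fold in females and 3.73-fold in males (males minus females -0.71 log2, permutation test, adjusted p = 0.00018). The retroperitoneal depot grew 4.20-fold and 5.06-fold (0.27, adjusted p = 0.0253). Glucose (0.36, adjusted p = 0.0009) and the liver fat fraction (0.13, adjusted p = 0.0133) rose more in males. Insulin (-0.88, adjusted p = 0.00018) and HDL cholesterol (-0.12, adjusted p = 0.0371) rose more in females. So did mesenteric fat (-0.20 g, adjusted p = 0.0142) and lean mass (-0.13, adjusted p = 0.0009).

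**Figure D1:**
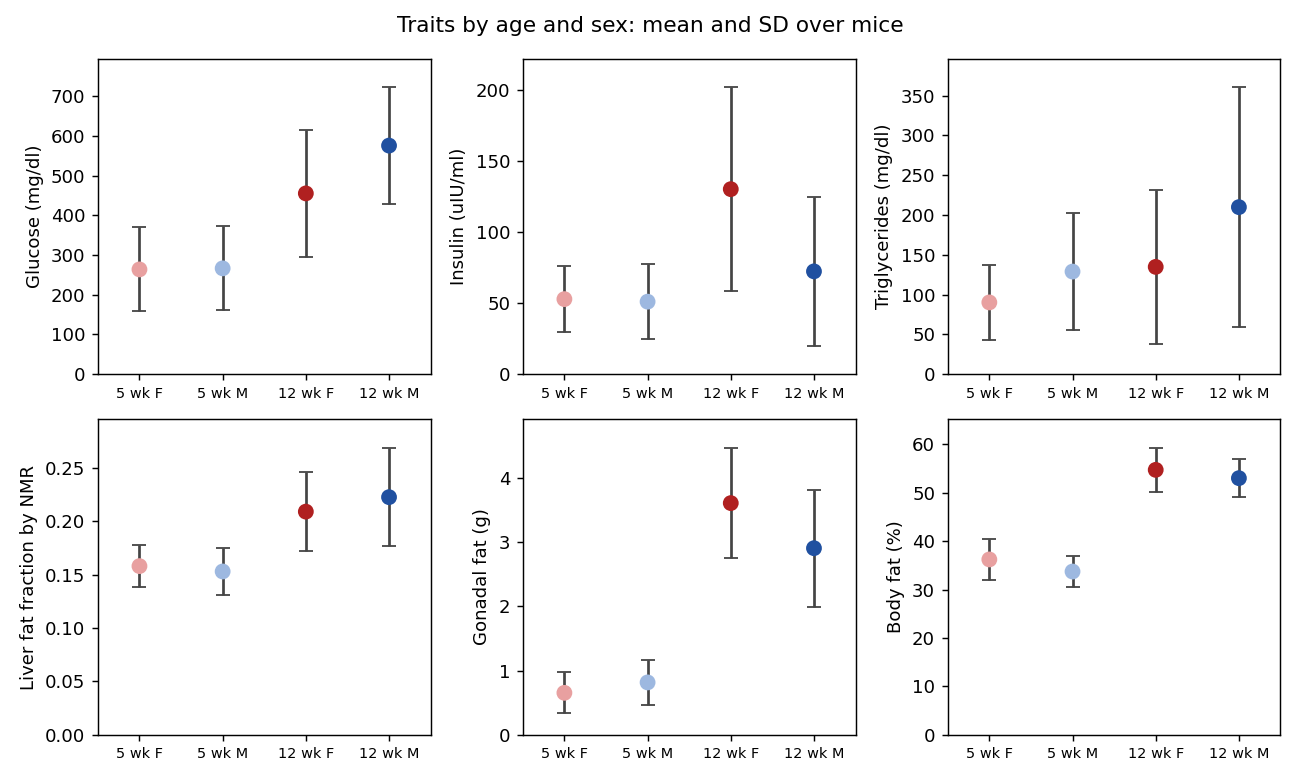
Mean and SD over mice of 6 traits (glucose in mg/dl, insulin in uIU/ml, triglycerides in mg/dl, liver fat fraction, gonadal fat in g, body fat in percent) in each of the 4 groups of 101 to 118 mice. At 12 weeks mean glucose is higher and mean insulin lower in males (575 mg/dl and 72.3 uIU/ml) than in females (455 mg/dl and 130.1 uIU/ml).

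At 12 weeks the mice with the highest glucose had the lowest insulin. The correlation on the log2 scale was negative in females (r = -0.588, permutation p = 1e-05, adjusted p = 4.4e-05, rho = -0.676, permutation p = 1e-05, adjusted p = 7.33e-05). It was negative in males as well (r = -0.329, permutation p = 0.00043, adjusted p = 0.00105, rho = -0.487, permutation p = 1e-05, adjusted p = 7.33e-05). Without the 2 mice farthest from the median glucose r was -0.579 and -0.399. Within batches 1 to 4 r was -0.628, -0.613, -0.453 and -0.552 in females. In males it was 0.325, -0.344, -0.295 and -0.450, so the relation was reversed in batch 1, which held 13 of them. The 5-week females had a negative r too, which did not pass by ranks (r = -0.256, permutation p = 0.0052, adjusted p = 0.00915, rho = -0.182, permutation p = 0.048, adjusted p = 0.0754), and the difference from 12 weeks was not tested. Batch values in them were -0.318, 0.110, -0.344 and -0.512, reversed in batch 2. The 5-week males had no detectable relation (r = 0.0613, adjusted p = 0.602). Of 44 correlations, 28 were called.

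In 12-week females insulin was related to other traits as well. Insulin and triglycerides were inversely related (r = -0.651, permutation p = 1e-05, adjusted p = 4.4e-05, rho = -0.598, permutation p = 1e-05, adjusted p = 7.33e-05). Batch values were -0.700, -0.675, -0.603 and -0.602. In 12-week males r was -0.321 (adjusted p = 0.00189) with batch values of 0.0242, -0.430, -0.329 and -0.192. In 5-week males it was positive, at 0.227 (adjusted p = 0.0353), which did not pass by ranks (rho = 0.192, adjusted p = 0.0839), with batch values of 0.247, -0.0429, 0.00371 and 0.512. In 5-week females it was 0.0123 (adjusted p = 0.916). The differences between groups were not tested. In 12-week females liver fat went with insulin (r = 0.485, permutation p = 1e-05, adjusted p = 4.4e-05, rho = 0.376, permutation p = 7e-05, adjusted p = 0.000257). Batch values were 0.431, 0.398, 0.687 and 0.418. Glucose measured at 5 weeks in these mice was inversely related to their insulin at 12 weeks (r = -0.433, permutation p = 1e-05, adjusted p = 4.4e-05, rho = -0.337, permutation p = 0.00049, adjusted p = 0.00103). Batch values were -0.0145, -0.618, -0.356 and -0.455, so this did not hold in batch 1. Without the 2 farthest mice these 3 relations had r = -0.609, 0.462 and -0.366. In 12-week males the last 2 had r = 0.476 (adjusted p = 4.4e-05) and -0.318 (adjusted p = 0.00218, batch 3 at 0.332). Glucose and triglycerides rose together in all 4 groups. In females r was 0.517 at 5 weeks and 0.563 at 12 weeks, with rho of 0.393 and 0.628 (adjusted p = 4.4e-05 for both). In males r was 0.378 (adjusted p = 0.000275) and 0.563 (adjusted p = 4.4e-05), with rho of 0.306 and 0.522. The lowest batch value of r was 0.0530, in batch 2 of the 5-week females, and every other batch lay at 0.205 or above.

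At 12 weeks lipid droplet genes were higher and matrix genes lower than at 5 weeks, in both sexes. In females Pex11a, which acts in peroxisome proliferation, was 2.29-fold higher at 12 weeks (1.19 ± 0.057 log2, limma adjusted p = 5.14e-65), Vnn1, a pantetheinase, 2.28-fold (1.19 ± 0.066) and the apolipoprotein Apoa4 2.25-fold (1.17 ± 0.078). Sparc, a secreted matrix glycoprotein, was 2.17-fold lower in females (-1.12 ± 0.040, adjusted p = 1.68e-94) and 2.40-fold lower in males (-1.26 ± 0.043, adjusted p = 9.88e-102). In males the largest gains were those of Rasgrp2 (1.12 ± 0.054), Vnn1 (1.08 ± 0.070), Prss8 (1.05 ± 0.058) and the acute phase glycoprotein Orm3 (1.05 ± 0.083). The other named genes higher at 12 weeks in females were Tbc1d31 (1.10), Retsat (0.98), Pnldc1 (0.93), Proca1 (0.92), Aacs (0.87), Aox1 (0.87) and Nap1l1 (0.85). In males they were Bmyc (0.92), Pex11a (0.91), Abcc4 (0.88), Nap1l1 (0.87), Tfcp2l1 (0.85) and Aox1 (0.82). Lower in females were the bile acid hydroxylase Cyp2c70 (-0.99 ± 0.047), Rdh9 (-1.05), Cdk1 (-1.01), Igfbp1 (-0.95), Apom (-0.94), Sult1d1 (-0.93), Cyp4f14 (-0.91), Rpl22l1 (-0.88) and C8b (-0.86). Lower in males were Cyp2c70 (-1.25), Cyp2c68 (-1.10), Apom (-1.06), Rpl22l1 (-1.02), Rdh9 (-0.97), Igfbp1 (-0.95), Mmp2 (-0.91), Plaat3 (-0.89) and Lum (-0.88). Limma called 6187 genes in females (2952 higher, 3235 lower) and 6198 in males (2982 higher, 3216 lower) of 13379. Most changes were small, with a median size of 0.12 and 0.13 among called genes, and 100 and 110 genes reached 1.5-fold. Many strongly varying liver genes were not measured. Across genes the male and female age effects correlated at r = 0.86 in separate mice, and 4372 of the 4442 genes called in both had the same sign. The sign was the same for 95.1, 97.5, 95.9 and 90.9% of the female calls and 95.1, 98.4, 95.0 and 95.7% of the male calls in batches 1 to 4 alone.

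Genes of the extracellular matrix were lower at 12 weeks. In females 12 of 16 were lower and 1 was higher (mean -0.46, adjusted p = 3.4e-17). In males 14 of 16 were lower and 1 was higher (mean -0.49, adjusted p = 5.28e-19). Counts adjusted over the list alone equalled those over all genes wherever they are not given. The gelatinase Mmp2 was at -0.79 ± 0.047 in females and -0.91 ± 0.050 in males, and the basement membrane collagen Col4a1 at -0.69 ± 0.038 and -0.68 ± 0.040. Cell cycle genes were lower too. In females 11 of 12 were lower (mean -0.39, adjusted p = 5.91e-12), and in males 10 of 12 were lower and 1 was higher (mean -0.28, adjusted p = 2.18e-06, adjusted p = 0.0566 with an estimated correlation). Cdk1, the mitotic kinase, was at -1.01 ± 0.049 and -0.80 ± 0.052. Of the sterol synthesis enzymes 13 of 17 were lower and 1 was higher in females (mean -0.38, adjusted p = 5.4e-09, adjusted p = 0.12 with an estimated correlation, 1 up and 15 down adjusted over the list alone). In males 13 of 17 were lower (mean -0.33, adjusted p = 2.18e-06, adjusted p = 0.207 with an estimated correlation). Idi1 was at -0.80 ± 0.071 in females, and Dhcr7 at -0.67 ± 0.051 and -0.58 ± 0.054. Of the interferon-stimulated genes 13 of 14 were lower in females (mean -0.33, adjusted p = 1.2e-08, adjusted p = 0.0803 with an estimated correlation). In males 13 of 14 were lower (mean -0.37, adjusted p = 1.42e-09, adjusted p = 0.0566 with an estimated correlation).

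Lipid droplet genes rose as a group. In females 11 of 11 were higher (mean 0.48, adjusted p = 5.91e-12). In males 9 of 11 were higher (mean 0.35, adjusted p = 1.1e-07). Plin2, a droplet coat protein, was at 0.61 ± 0.042 in females, the droplet assembly factor Fitm2 at 0.55 ± 0.037 and 0.47 ± 0.040, and the fatty acid transporter Cd36 at 0.49 ± 0.039 in males. Fatty acid oxidation genes were more mixed. In females 12 of 19 were higher and 3 were lower (mean 0.10, adjusted p = 0.00211, adjusted p = 0.287 with an estimated correlation, 12 up and 4 down adjusted over the list alone). In males 9 of 19 were higher and 4 were lower (mean 0.10, adjusted p = 0.00482, adjusted p = 0.228 with an estimated correlation, 10 up and 4 down adjusted over the list alone). Of the xenobiotic metabolism genes 16 of 28 were higher and 4 were lower in males (mean 0.091, adjusted p = 0.00291, adjusted p = 0.218 with an estimated correlation). Glutathione transferase Gsta2 was at 0.72 ± 0.061 and Cyp1a2 at -0.54 ± 0.050. Of the immature liver genes 4 of 7 were lower in females (mean -0.17, adjusted p = 0.0252, adjusted p = 0.0803 with an estimated correlation). Of the oxidative phosphorylation genes in females 23 of 46 were lower and 6 were higher (mean -0.028, adjusted p = 0.0493, adjusted p = 0.601 with an estimated correlation, 6 up and 24 down adjusted over the list alone).

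Of the macrophage markers 11 of 19 were lower and 2 were higher in females (mean -0.11, adjusted p = 0.0297, adjusted p = 0.601 with an estimated correlation). In males 15 of 19 were lower and 2 were higher (mean -0.20, adjusted p = 3.31e-05, adjusted p = 0.218 with an estimated correlation). Of the neutrophil markers 6 of 9 were lower in males (mean -0.19, adjusted p = 0.00291, adjusted p = 0.169 with an estimated correlation). Of the lymphocyte markers 10 of 16 were lower in males (mean -0.13, adjusted p = 0.0119, adjusted p = 0.226 with an estimated correlation). Hepatocyte markers were lower on average. In females 8 of 14 were lower and 3 were higher (mean -0.081, adjusted p = 0.0145, adjusted p = 0.12 with an estimated correlation, 3 up and 9 down adjusted over the list alone). In males 7 of 14 were lower and 2 were higher (mean -0.078, adjusted p = 0.0164, adjusted p = 0.169 with an estimated correlation, 3 up and 8 down adjusted over the list alone). Stellate cell markers were called in none of the 19 comparisons. Their mean was 0.097 in females (camera adjusted p = 0.197) and 0.039 in males (adjusted p = 0.704). The same held for circadian clock genes, with means of 0.055 (adjusted p = 0.476) and 0.13 (adjusted p = 0.147).

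**Figure D2:**
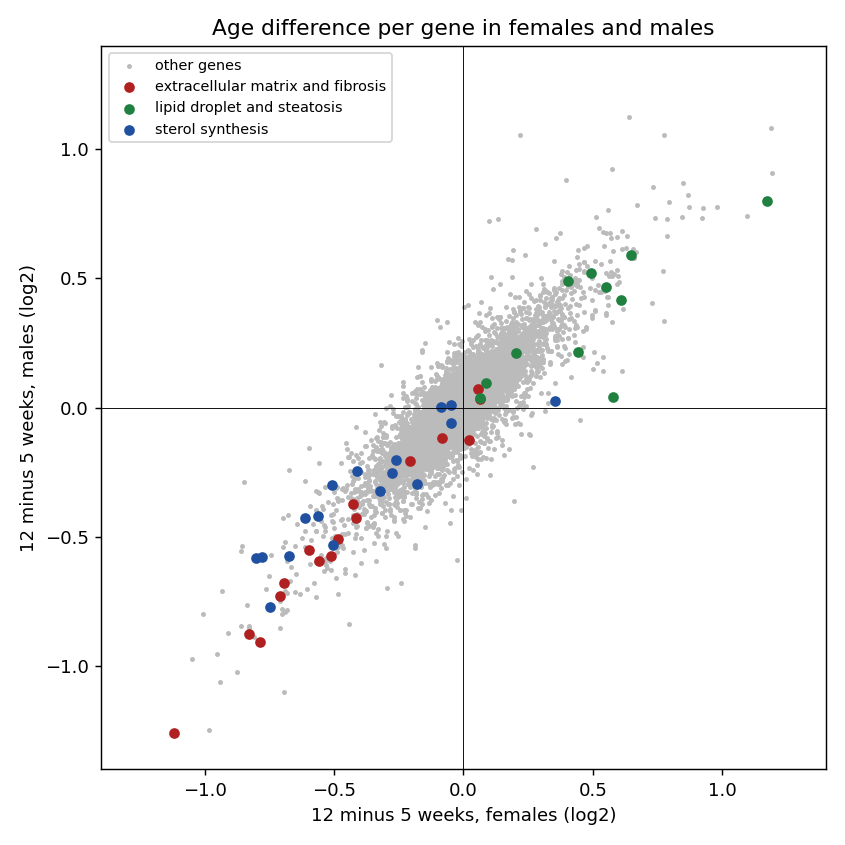
Log2 difference between 12 and 5 weeks per gene in females (x axis) and males (y axis), each point 1 of 13379 genes. Matrix genes (red) and sterol synthesis genes (blue) lie mostly below 0 in both sexes, with means of -0.46 and -0.38 in females, and lipid droplet genes (green) above 0, with a mean of 0.48 in females.

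Cyp2d9, a steroid hydroxylase of male mouse liver, was 2.08-fold higher in males at 5 weeks (1.06 ± 0.083 log2, limma adjusted p = 2.18e-28) and 2.57-fold at 12 weeks (1.36 ± 0.084, adjusted p = 5.33e-43). Keg1 (0.92 ± 0.086 and 0.57 ± 0.087), the complement component C8b (0.72 ± 0.076 and 0.74 ± 0.076) and the haem synthesis enzyme Alas2 (0.71 ± 0.063 and 0.51 ± 0.063) were also higher in males at both ages. The X-linked Eif2s3x was lower in males at both ages (-0.60 ± 0.017 and -0.60 ± 0.018), as was the zinc transporter Slc39a5 (-0.54 ± 0.059 and -0.74 ± 0.060). At 5 weeks Ttc39c (0.68), C8a (0.62), Serpina11 (0.48), Gstp1 (0.47), F11 (0.47) and Hhex (0.46) were higher and Rasgrp2 (-0.63), Bex4 (-0.58), Mmd2 (-0.57), 5530601H04Rik (-0.56), Esrrg (-0.54), Cd83 (-0.54), Rdh16f2 (-0.52) and Slc16a5 (-0.52) lower in males. At 12 weeks Ttc39c (0.70), 9130409I23Rik (0.63), Susd4 (0.57), Cyp2c54 (0.55), Cyp2c55 (0.43) and Sdcbp2 (0.42) were higher and Itga6 (-0.70), Gsn (-0.66), Acly (-0.65), Mmd2 (-0.64), Rcan2 (-0.60), Emp2 (-0.59), Rdh16f2 (-0.59) and Cyp2c68 (-0.55) lower. Limma called 3336 genes at 5 weeks (1407 higher and 1929 lower in males) and 2415 at 12 weeks (1200 and 1215), of which 8 and 13 reached 1.5-fold. Of the 1126 genes called at both ages, 1026 had the same sign. In batches 1 to 4 alone 98.4, 97.8, 98.5 and 93.5% of the calls at 5 weeks and 91.5, 99.9, 91.6 and 97.1% of those at 12 weeks had the same sign. Without batch 2, 1307 genes were called at 12 weeks.

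Male-biased genes and sex chromosome genes had the largest mean shifts of the 32 lists at both ages. All 4 sex chromosome genes were lower in males at 5 weeks (mean -0.37, camera adjusted p = 1.07e-24) and at 12 weeks (mean -0.36, adjusted p = 2.14e-29). At 5 weeks Kdm5c was at -0.39 ± 0.030, Ddx3x at -0.28 ± 0.028 and Kdm6a at -0.20 ± 0.029. Of the male-biased genes 6 of 7 were higher in males at 5 weeks (mean 0.51, adjusted p = 2.29e-18). At 12 weeks 5 of 7 were higher (mean 0.41, adjusted p = 3.58e-12). Of the female-biased genes 3 of 6 were lower at 5 weeks (mean -0.13, adjusted p = 0.0192, adjusted p = 0.247 with an estimated correlation). At 5 weeks 11 of 17 sterol synthesis enzymes were lower in males (mean -0.17, adjusted p = 7.6e-07, adjusted p = 0.246 with an estimated correlation, 12 down adjusted over the list alone). At 12 weeks 8 of 17 were lower (mean -0.12, adjusted p = 0.000328, adjusted p = 0.405 with an estimated correlation, 9 down adjusted over the list alone). Of the fatty acid synthesis genes 11 of 16 were lower in males at 12 weeks (mean -0.22, adjusted p = 1.06e-08, 12 down adjusted over the list alone). ATP citrate lyase Acly was at -0.65 ± 0.096 and acetyl-CoA carboxylase Acaca at -0.43 ± 0.082. At 5 weeks 7 of 16 were lower (mean -0.11, adjusted p = 0.0166, adjusted p = 0.512 with an estimated correlation). Of the xenobiotic metabolism genes 15 of 28 were higher and 2 were lower in males at 12 weeks (mean 0.11, adjusted p = 2.41e-09, 16 up and 2 down adjusted over the list alone).

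Immune cell markers were lower in males at 12 weeks. Of the macrophage markers 16 of 19 were lower (mean -0.17, adjusted p = 3.58e-12, 17 down adjusted over the list alone). Of the lymphocyte markers 9 of 16 were lower (mean -0.11, adjusted p = 4.18e-07). Of the neutrophil markers 5 of 9 were lower (mean -0.13, adjusted p = 1.35e-05). At 5 weeks 7 of 19 were lower among the macrophage markers (mean -0.083, adjusted p = 0.014, adjusted p = 0.519 with an estimated correlation, 1 up and 12 down adjusted over the list alone). Erythroid markers passed at 5 weeks through Alas2 alone, as 1 of 3 was higher (mean 0.25, adjusted p = 0.014). Of the unfolded protein response genes at 5 weeks 8 of 25 were higher and 4 were lower (mean 0.054, adjusted p = 0.0337, adjusted p = 0.512 with an estimated correlation, 10 up and 6 down adjusted over the list alone). Of the immediate early genes 6 of 13 were lower at 5 weeks (mean -0.12, adjusted p = 0.014, adjusted p = 0.31 with an estimated correlation, 7 down adjusted over the list alone). Of the endothelial markers 7 of 15 were lower and 1 was higher at 5 weeks (mean -0.052, adjusted p = 0.014, adjusted p = 0.191 with an estimated correlation).

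The age effect differed between males and females for 1145 genes. It was more positive in males for 768 and more negative for 377. Orm3 had the largest difference (0.84 ± 0.11 log2, 1.78-fold, limma adjusted p = 9.27e-10). The glutathione transferase Gsta2 (0.63 ± 0.082), the stress pseudokinase Trib3 (0.60 ± 0.089) and the efflux transporter Abcc4 (0.48 ± 0.090) were among those more positive in males. The pentraxin Apcs (-0.56 ± 0.096), Serpina11 (-0.56 ± 0.15) and G0s2, an inhibitor of triglyceride lipase (-0.54 ± 0.11), were among those more negative. Of the xenobiotic metabolism genes 13 of 28 were more positive (mean 0.17, adjusted p = 2.64e-13, 19 up adjusted over the list alone). Of the neutrophil markers 5 of 9 were more negative (mean -0.13, adjusted p = 1.05e-05). Of the bile acid and sterol transport genes 3 of 18 were more positive and 1 was more negative (mean 0.058, adjusted p = 0.0247, adjusted p = 0.151 with an estimated correlation, 5 up and 1 down adjusted over the list alone). Acute phase genes went both ways, as 6 of 20 were more negative and 2 were more positive (mean -0.011, adjusted p = 0.00254, adjusted p = 0.343 with an estimated correlation). Orm3 rose more in males, while Itih4 (-0.20 ± 0.033) and haptoglobin Hp (-0.14 ± 0.032) were more negative. The sign was the same for 97.6, 97.6, 93.3 and 96.0% of the calls in batches 1 to 4 alone. The count fell to 624 without batch 1 and 736 without batch 2.

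At 12 weeks mice with higher glucose had more transcript of xenobiotic metabolism genes, with or without insulin in the fit. An SD of glucose was 1.49-fold in females and 1.37-fold in males (n = 216 in all). Scd1, the stearoyl-CoA desaturase, fell by 0.41 log2 per SD (SE 0.079, limma adjusted p = 2.25e-05). Mmd2 (0.29 ± 0.035, adjusted p = 5.81e-12), nicotinamide methyltransferase Nnmt (0.28 ± 0.032), carbonic anhydrase Car1 (0.26 ± 0.031) and Gsta2 (0.26 ± 0.029) rose. So did Mogat2 (0.25), Orm2 (0.24), Igfbp5 (0.23), Flacc1 (0.22), Bex4 (0.21) and Cyp2c37 (0.21). The other named genes that fell were Csrp3 (-0.25), Rflna (-0.24), Apoa1 (-0.22), Spon2 (-0.21), Gpam (-0.21), Pdzk1ip1 (-0.20), Prxl2a (-0.20), Elovl2 (-0.20) and Kcnh3 (-0.20). Limma called 1728 genes (992 higher, 736 lower). Of the xenobiotic metabolism genes 15 of 28 rose and 1 fell with glucose (mean 0.056, adjusted p = 1.79e-08, 16 up and 3 down adjusted over the list alone). Of the gluconeogenic and other insulin-repressed genes 7 of 12 rose (mean 0.058, adjusted p = 5.75e-06, 8 up adjusted over the list alone). Of the fatty acid synthesis genes 9 of 16 fell (mean -0.096, adjusted p = 1.21e-06, adjusted p = 0.167 with an estimated correlation, 10 down adjusted over the list alone). With insulin in the fit the mean glucose slope of fatty acid synthesis was 0.0044 (camera adjusted p = 0.985). That of the gluconeogenic and other insulin-repressed genes was 0.014 (adjusted p = 0.0747). Both calls and that of Scd1 were thus lost, and 949 genes were called. Lists that passed only then, at the preset correlation, were sterol synthesis (mean from -0.00099 to 0.045, adjusted p = 0.00271), glycolysis (from -0.0022 to 0.025, adjusted p = 0.00245) and fatty acid oxidation (from -0.014 to -0.022, adjusted p = 0.0048). No correlation was estimated in that fit. The xenobiotic metabolism mean was then 0.041 (adjusted p = 1.42e-06). The sign was the same for 77.4, 99.9, 98.0 and 88.2% of the calls in batches 1 to 4 alone. Without batch 2, 549 genes were called.

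An SD of insulin was 2.13-fold in females and 2.32-fold in males (n = 216 in all). Scd1 rose by 0.82 ± 0.062 log2 per SD (1.77-fold, limma adjusted p = 1.9e-25), Acaca by 0.46 ± 0.035, Acly by 0.45 ± 0.039 and the acyltransferase Gpam by 0.37 ± 0.032. Other named genes that rose were Spon2 (0.40), Anxa2 (0.37), 2010003K11Rik (0.35), Aqp8 (0.35), Rflna (0.34) and Pgd (0.32). Igfbp1, a secreted protein that insulin represses (-0.32 ± 0.052), and the coactivator Ppargc1a (-0.26 ± 0.031) fell. So did Car1 (-0.35), Cyp2c37 (-0.31), Cyp2c54 (-0.30), Dleu2 (-0.28), Nnmt (-0.26), Mmd2 (-0.25), Gsta2 (-0.23) and Cyp2b10 (-0.23). Limma called 3680 genes (1797 higher, 1883 lower). Of the fatty acid synthesis genes 13 of 16 rose with insulin (mean 0.22, adjusted p = 1.74e-19). Of the gluconeogenic genes 8 of 12 fell (mean -0.10, adjusted p = 4.49e-07, 9 down adjusted over the list alone). Of the interferon-stimulated genes 11 of 14 rose (mean 0.099, adjusted p = 2.4e-08, 12 up adjusted over the list alone). Of the female-biased genes 5 of 6 fell (mean -0.11, adjusted p = 0.000248). Hepatocyte markers fell on average, as 8 of 14 fell and 2 rose (mean -0.021, adjusted p = 0.000248). Of the matrix genes 9 of 16 rose (mean 0.051, adjusted p = 0.000564, adjusted p = 0.181 with an estimated correlation, 10 up adjusted over the list alone). Across genes, which are not independent, the glucose and insulin slopes of these same mice correlated at r = -0.70, against a median of -0.46 and a lowest of -0.64 over 99 shuffles of the traits together among mice of 1 sex and batch, which keep the correlation of the traits. Of 1169 genes called in both, 3 had the same sign. In batches 1 to 4 alone 83.3, 99.9, 91.8 and 94.1% of the calls had the same sign. Without batch 2, 1810 genes were called.

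Scd1 fell with triglycerides (-0.70 ± 0.068 per SD, limma adjusted p = 2.33e-17) and rose with cholesterol (0.63 ± 0.074) and the liver fat fraction (0.72 ± 0.067). With triglycerides, Mmd2 (0.32), Cyp2c54 (0.32), Car1 (0.29), Nnmt (0.29) and Igfbp5 (0.29) rose and 2010003K11Rik (-0.29), Rflna (-0.29), Gpam (-0.29) and Csrp3 (-0.28) fell. With cholesterol, Acaca (0.33), Anxa2 (0.26), 2010003K11Rik (0.24) and Mtmr11 (0.24) rose and C8b (-0.34), Lifr (-0.24), Slc3a1 (-0.22), Kyat1 (-0.21) and Cyp4f14 (-0.21) fell. With liver fat, 2010003K11Rik (0.43), Apoa4 (0.42), Acaca (0.40) and Anxa2 (0.40) rose and Cyp2c54 (-0.37), C8b (-0.34), Car1 (-0.34), Lifr (-0.28) and Nnmt (-0.27) fell. Fatty acid synthesis genes fell with triglycerides, as 12 of 16 fell (mean -0.15, adjusted p = 5.57e-12). With cholesterol 12 of 16 rose (mean 0.15, adjusted p = 2.83e-13). With liver fat 10 of 16 rose (mean 0.18, adjusted p = 4.44e-13). With liver fat 8 of 11 lipid droplet genes rose (mean 0.11, adjusted p = 3.44e-10). With triglycerides 6 of 11 fell (mean -0.093, adjusted p = 4.04e-07, 7 down adjusted over the list alone). With liver fat 13 of 16 matrix genes rose (mean 0.072, adjusted p = 1.11e-08, 14 up adjusted over the list alone). So did 5 of 11 glycolysis genes (mean 0.061, adjusted p = 7.92e-05). Adipocyte markers passed with cholesterol, as 2 of 5 rose (mean 0.047, adjusted p = 0.027, adjusted p = 0.121 with an estimated correlation).

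Limma called 2623 genes for triglycerides (1428 higher, 1195 lower), 1816 for cholesterol (812 and 1004) and 3475 for liver fat (1742 and 1733), with n = 216, 216 and 215. Without batch 2 the counts were 1052, 838 and 2077, and without batch 3 that for cholesterol was 1207. In females only the cholesterol count was 269 and in males only 971, a difference that was not tested. The share of calls with the same sign in batches 1 to 4 alone was 92.4, 100, 94.4 and 87.8% for triglycerides, 90.8, 99.7, 98.6 and 95.7% for cholesterol and 90.8, 99.9, 97.1 and 96.7% for liver fat. Across genes the triglyceride and glucose slopes correlated at r = 0.85 over the same mice, against a median of 0.57 and a highest of 0.70 with the traits shuffled together. For liver fat and insulin r was 0.82, against 0.51 and 0.70.

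Body fat percent at 12 weeks went with lower male-biased transcripts. Keg1 fell by 0.37 log2 per SD of body fat (SE 0.044, limma adjusted p = 1.63e-11), with C8b (-0.28), Hsd17b6 (-0.24), C8a (-0.22) and Alas2 (-0.21), and Orm2 (0.25), Nfe2l2 (0.20), Mmd2 (0.20), Orm3 (0.20) and Abcc4 (0.19) rose. Of the male-biased genes 5 of 7 fell (mean -0.13, adjusted p = 2.08e-10). Limma called 902 genes, of which 90.1, 100, 97.2 and 98.2% had the same sign in batches 1 to 4 alone. The slope was called for 1077 genes in females only and 6 in males only, a difference that was not tested, and for 435, 546 and 379 genes without batch 2, 3 or 4. With body weight as a covariate it was called for 1653.

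At 5 weeks Vnn1 rose with cholesterol (0.32 ± 0.030 per SD, n = 219, limma adjusted p = 6.22e-18), body fat (0.27 ± 0.032), triglycerides (0.20 ± 0.034), glucose (0.19 ± 0.035) and liver fat (0.20 ± 0.035). With glucose, Cyp3a13 (0.21), Orm2 (0.19), Dusp1 (0.18) and Apoa4 (0.17) also rose and Idi1 (-0.18), Fdps (-0.17), Pmvk (-0.16), Rpl22l1 (-0.16) and Apom (-0.15) fell. With triglycerides, Apoa4 (0.28), Slc34a2 (0.26), Rgs5 (0.21) and Bmyc (0.20) rose and Igfbp1 (-0.22), Sqle (-0.19), Rdh9 (-0.18), Lss (-0.18) and Fdps (-0.18) fell. With cholesterol, Apoa4 (0.30), Retsat (0.25), 2010003K11Rik (0.25) and Pex11a (0.22) rose and Mmp2 (-0.21), Idi1 (-0.21), Sqle (-0.21), Igfbp1 (-0.21) and Lss (-0.20) fell. Body fat went with Orm3 (0.31), Orm2 (0.30), Ugt3a1 (0.22) and Rasgrp2 (0.21) upward and Mmp2 (-0.20), C8b (-0.18), F11 (-0.18), Igfbp1 (-0.18) and Akr1c18 (-0.18) downward. Liver fat went with Rab30 (0.20), G0s2 (0.18), Retsat (0.18) and Plin5 (0.17) upward and Mid1ip1 (-0.17), C8b (-0.16), Phlda1 (-0.15), Sdf2l1 (-0.14) and Bcat2 (-0.13) downward. Insulin had the fewest calls at 5 weeks, with Grk5 (0.19), Sdr9c7 (0.16), Fam47e (0.15), Tedc2 (0.15) and Slc34a2 (0.15) rising and Cyp3a13 (-0.22), Bhlhb9 (-0.14), Ube2s (-0.14), Abcg5 (-0.13) and Cabcoco1 (-0.13) falling. In males only 205 genes were called for insulin and in females only 2 (limma), and for liver fat 278 and 103; whether the slopes differed between the sexes was not tested. Limma called 1087 genes for glucose, 328 for insulin, 1947 for triglycerides, 2410 for cholesterol, 749 for liver fat and 1843 for body fat.

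Sterol synthesis genes fell with 5-week cholesterol, as 15 of 17 fell (mean -0.12, adjusted p = 4.69e-15, 1 up and 15 down adjusted over the list alone). With triglycerides 12 of 17 fell (mean -0.095, adjusted p = 2.37e-12, adjusted p = 0.0673 with an estimated correlation, 1 up and 14 down adjusted over the list alone). With glucose 9 of 17 fell (mean -0.088, adjusted p = 9.25e-12, adjusted p = 0.0749 with an estimated correlation, 12 down adjusted over the list alone). Fatty acid oxidation genes rose with liver fat, as 12 of 19 rose (mean 0.054, adjusted p = 8.3e-25, 15 up adjusted over the list alone). With cholesterol 11 of 19 rose (mean 0.053, adjusted p = 3e-12). Lipid droplet genes rose with cholesterol, as 8 of 11 rose (mean 0.13, adjusted p = 1.38e-14). With liver fat 8 of 11 rose (mean 0.097, adjusted p = 7.85e-15, 9 up adjusted over the list alone). Matrix genes fell with body fat, as 11 of 16 fell (mean -0.079, adjusted p = 9.49e-16). So did 7 of 12 cell cycle genes (mean -0.075, adjusted p = 3.12e-08, 8 down adjusted over the list alone). Heat shock genes rose with insulin, as 3 of 11 rose (mean 0.041, adjusted p = 5.71e-05, 5 up adjusted over the list alone). Immature liver genes fell with insulin, as 2 of 7 fell (mean -0.050, adjusted p = 0.000106, 4 down adjusted over the list alone). Of the cholangiocyte markers 1 of 7, Epcam (-0.059 ± 0.015), fell with insulin (mean -0.022, adjusted p = 0.0249, adjusted p = 0.221 with an estimated correlation). Skeletal muscle markers shifted with liver fat, as 2 of 6 fell (mean -0.088, adjusted p = 3.65e-05, adjusted p = 0.207 with an estimated correlation, 6 down adjusted over the list alone). Of the acinar markers Cela1 (-0.11 ± 0.021) fell with liver fat, as 1 of 2 fell (mean -0.057, adjusted p = 0.0278, adjusted p = 0.0718 with an estimated correlation).

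The share of 5-week calls with the same sign in batches 1 to 4 alone was 93.8, 95.0, 98.7 and 99.2% for glucose, 97.0, 96.6, 99.7 and 99.7% for insulin and 98.6, 84.2, 98.8 and 97.6% for triglycerides. It was 98.9, 87.6, 97.8 and 95.2% for cholesterol, 98.8, 92.1, 99.3 and 98.7% for liver fat and 93.5, 85.4, 99.3 and 96.9% for body fat. With body weight as a covariate the counts fell to 406 for glucose, 178 for insulin, 522 for triglycerides, 716 for cholesterol and 1214 for body fat. Igfbp1 then turned positive with cholesterol (0.042) and with body fat (0.059). The mean of sterol synthesis in the body fat slope turned from -0.075 to 0.0065 (adjusted p = 0.119 with an estimated correlation before). That of matrix genes in the triglyceride slope turned from -0.034 to 0.013 (adjusted p = 0.267 with an estimated correlation before). Without batch 2, 3 or 4 the insulin count was 144, 35 and 104. Without batch 1, 3 or 4 the liver fat count was 408, 268 and 420. The glucose count was 721 without batch 3 and 405 without batch 4. The triglyceride count was 936 and the cholesterol count 1535 without batch 1, and the body fat count 1015 without batch 3.

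**Figure D3:**
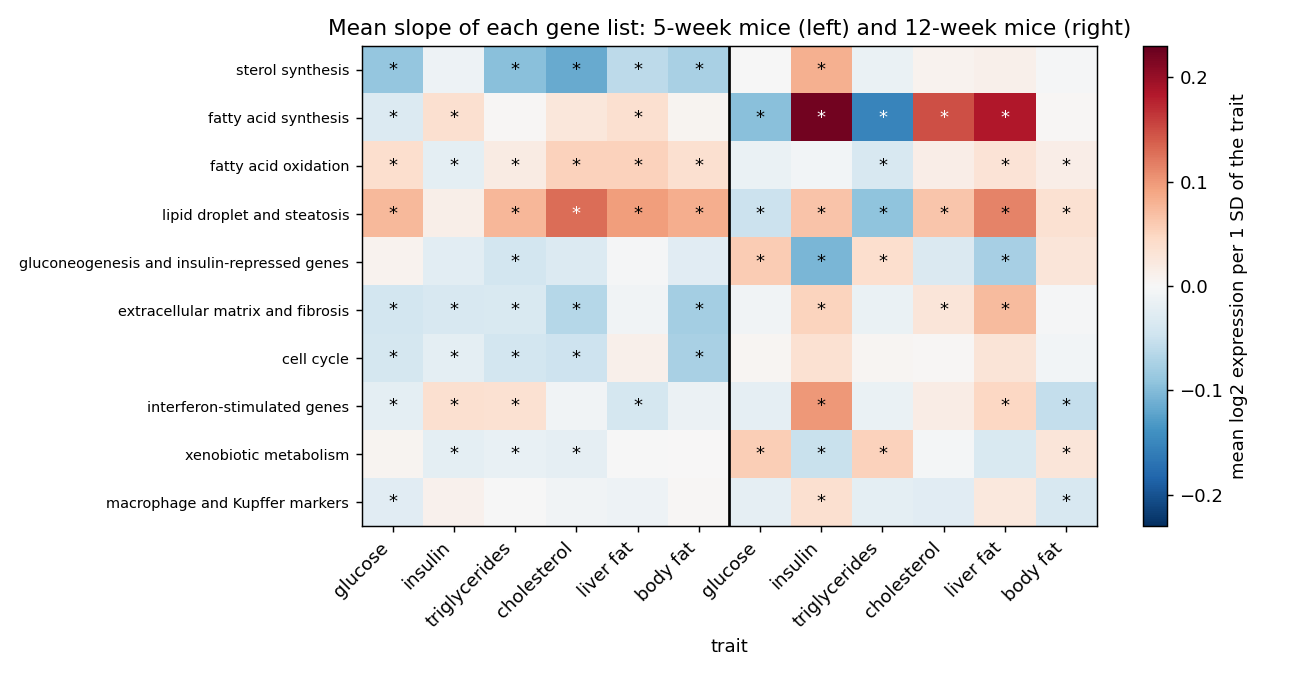
Mean log2 slope per SD of 6 traits for 10 gene lists at 5 weeks (left) and 12 weeks (right), with an asterisk where the camera adjusted p was under 0.05. Fatty acid synthesis at 12 weeks is positive with insulin (0.22) and negative with glucose (-0.096) and triglycerides (-0.15).

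The 12-week glucose slope differed between the sexes for 334 genes (167 more positive and 167 more negative in males). Among those more positive in males were Keg1 (0.50 ± 0.095), Fdps (0.40 ± 0.084) and Acly (0.39 ± 0.094). Among those more negative were Orm2 (-0.37 ± 0.084), D630004K10Rik (-0.30 ± 0.067) and Apoa4 (-0.30 ± 0.081). The limma adjusted p was 0.000277 for Keg1 and 0.00381 for Orm2. Of the sterol synthesis genes 8 of 17 were more positive (mean 0.15, adjusted p = 2.39e-15, 14 up adjusted over the list alone). Of the fatty acid oxidation genes 6 of 19 were more negative (mean -0.065, adjusted p = 5.79e-11, 10 down adjusted over the list alone). Of the lipid droplet genes 4 of 11 were more negative (mean -0.10, adjusted p = 2.17e-06, 6 down adjusted over the list alone). The sign was the same for 78.4, 100, 98.8 and 80.5% of the calls in batches 1 to 4 alone. The count dropped to 218, 41 and 136 without batch 1, 2 or 3. It dropped to 106 with unlogged glucose and to 57 with normal scores.

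The glucose slope differed between 12 and 5 weeks for 881 genes (440 more positive and 441 more negative at 12 weeks). Among those more positive at 12 weeks were Mmd2 (0.29 ± 0.047), Idi1 (0.26 ± 0.050) and Cyp2c54 (0.25 ± 0.044). Among those more negative were Scd1 (-0.40 ± 0.082), Vnn1 (-0.35 ± 0.045) and Apoa4 (-0.33 ± 0.055). The limma adjusted p was 7.05e-07 for Mmd2 and 0.000179 for Scd1. Of the lipid droplet genes 7 of 11 were more negative (mean -0.12, adjusted p = 8.01e-10). Of the fatty acid oxidation genes 8 of 19 were more negative (mean -0.051, adjusted p = 3.32e-09, 1 up and 11 down adjusted over the list alone). Of the xenobiotic metabolism genes 10 of 28 were more positive (mean 0.050, adjusted p = 5.16e-06, 13 up and 3 down adjusted over the list alone). So were 7 of 17 sterol synthesis genes (mean 0.090, adjusted p = 8.4e-09, adjusted p = 0.122 with an estimated correlation, 10 up adjusted over the list alone). Across genes the glucose slopes at 5 and 12 weeks correlated at r = 0.25. In batches 1 to 4 alone 83.8, 99.1, 98.6 and 91.4% of the calls had the same sign. The count was 275 without batch 2, 586 without batch 3 and 339 with body weight as a covariate. In females only, with 190 calls, the sterol synthesis mean turned negative (-0.016).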

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

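The differences between sexes or ages given first were singled out by a test of the difference itself. The lower matrix genes, the likeness of the 5-week slopes to the age difference and the 8 arrays whose X-linked genes go against the sex label were noticed in the data. The slope differences of the traits other than glucose, the slopes per unit of a trait, the age by sex tests of traits, and the tests of the matrix genes, of body weight and array batch and of the sex labels were chosen after the results were seen.

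The age effect differed between the sexes for 1145 genes (limma). The difference, males minus females, was positive for Orm3 (0.84), Gsta2 (0.63), Trib3 (0.60), Bex4 (0.56), Cirbp (0.48), Abcc4 (0.48), Rasgrp2 (0.48), Rhbg (0.44), Cyp2c54 (0.44) and Cd83 (0.43). It was negative for Apcs (-0.56), Serpina11 (-0.56), G0s2 (-0.54), Fgl1 (-0.50), Slc25a30 (-0.50), Spon2 (-0.47), 2010003K11Rik (-0.44), Cyp2c68 (-0.41), Celsr1 (-0.40) and Fam25c (-0.39). By list means it was positive for xenobiotic metabolism (0.17, adjusted p = 2.64e-13) and negative for neutrophil markers (-0.13, adjusted p = 1.05e-05). The calls of the other lists were lost with an estimated correlation. Their means were positive for bile acid and sterol transport (0.058, adjusted p = 0.151 with an estimated correlation, 3 called more positive and 1 more negative) and cell cycle genes (0.11, adjusted p = 0.242 with an estimated correlation). They were negative for fatty acid synthesis (-0.11, adjusted p = 0.475 with an estimated correlation), lipid droplet genes (-0.12, adjusted p = 0.343 with an estimated correlation), male-biased genes (-0.096, adjusted p = 0.343 with an estimated correlation), acute phase genes (-0.011, adjusted p = 0.343 with an estimated correlation, 2 called more positive and 6 more negative), macrophage markers (-0.083, adjusted p = 0.343 with an estimated correlation) and lymphocyte markers (-0.060, adjusted p = 0.343 with an estimated correlation).

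The 12-week glucose slope differed between the sexes for 334 genes. The difference, males minus females, was positive for Keg1 (0.50), Fdps (0.40), Acly (0.39), Camk1d (0.39) and Aqp8 (0.37). It was negative for Orm2 (-0.37), D630004K10Rik (-0.30), Apoa4 (-0.30), Orm3 (-0.28) and Chrna2 (-0.27). List means were positive for sterol synthesis (0.15, adjusted p = 2.39e-15), and negative for fatty acid oxidation (-0.065, adjusted p = 5.79e-11) and lipid droplet genes (-0.10, adjusted p = 2.17e-06). Means whose call was lost with an estimated correlation were those of fatty acid synthesis (0.092, adjusted p = 0.363 with an estimated correlation), male-biased genes (0.13, adjusted p = 0.212 with an estimated correlation) and interferon-stimulated genes (0.088, adjusted p = 0.25 with an estimated correlation). Between ages the glucose slope differed for 881 genes. The difference, 12 minus 5 weeks, was positive for Mmd2 (0.29), Idi1 (0.26), Cyp2c54 (0.25), Rdh16f2 (0.24) and Sqle (0.24). It was negative for Scd1 (-0.40), Vnn1 (-0.35), Apoa4 (-0.33), 2010003K11Rik (-0.28) and Pnldc1 (-0.28). List means were positive for immature liver genes (0.047, adjusted p = 0.00512), xenobiotic metabolism (0.050, adjusted p = 5.16e-06) and hepatocyte markers (0.017, adjusted p = 0.000607, 3 called more positive and 1 more negative). They were negative for fatty acid oxidation (-0.051, adjusted p = 3.32e-09) and lipid droplet genes (-0.12, adjusted p = 8.01e-10). Calls lost with an estimated correlation were, with positive means, sterol synthesis (0.090, adjusted p = 0.122 with an estimated correlation), gluconeogenic genes (0.050, adjusted p = 0.26 with an estimated correlation, 1 called more positive and 1 more negative), cell cycle genes (0.046, adjusted p = 0.269 with an estimated correlation) and matrix genes (0.038, adjusted p = 0.361 with an estimated correlation). With a negative mean there was fatty acid synthesis (-0.070, adjusted p = 0.37 with an estimated correlation). The fatty acid synthesis mean turned positive with insulin in the fit (0.025) and in males only (0.017), and the sterol synthesis mean turned negative in females only (-0.016).

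The slopes of the other traits also differed between ages, for 1770 genes with insulin, 2149 with triglycerides, 1229 with cholesterol, 1692 with liver fat and 488 with body fat. Without the arrays whose X-linked genes go against the sex label these counts were 1852, 2038, 1185, 1692 and 443. Per log2 unit of the trait (per percent point for body fat) in place of 1 SD they were 794, 2033, 1269, 972 and 560. In batches 1 to 4 alone 90.1 to 99.8% of the calls per SD had the same sign. Across genes, the slopes at the 2 ages correlated at r = 0.32, 0.010, 0.35, 0.34 and 0.37. Of the traits, the log2 age difference in males minus females was 0.36 for glucose, -0.88 for insulin, -0.12 for HDL cholesterol, -0.13 for lean mass, -0.71 for gonadal fat, 0.27 for retroperitoneal fat and 0.13 for the liver fat fraction. For mesenteric fat it was -0.20 g.

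Chance assignment of the mice was tested for the 12 differences below, not for slopes within an age or alternative settings. Of 100 splits, the real one included, only that one called as many genes for each difference, which argues against chance. The real count against the highest of the other splits was 6187 against 1 for age in females, 6198 against 16 for age in males, 3336 against 7 for sex at 5 weeks, 2415 against 53 for sex at 12 weeks and 1145 against 1 for the interaction. For the glucose slope it was 334 against 60 between the sexes and 881 against 67 between ages. For the other slope differences between ages it was 1770 against 35 with insulin, 2149 against 14 with triglycerides, 1229 against 1 with cholesterol, 1692 against 6 with liver fat and 488 against 1 with body fat.

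The matrix genes were lower at 12 weeks, at a mean of -0.47 log2 over both sexes (SE 0.016). A smaller share of all non-parenchymal cells would lower the endothelial markers, which were at -0.029 (SE between members 0.035), and fewer stellate cells would lower their markers outside the list, which were at 0.068 (SE between members 0.063); both lie above 50% of the matrix change by more than 2 SE, which argues against these as the main cause. Array batch or scaling as the whole cause is argued against too, since the mean nearest to 0 over the 4 batches alone and 2 scalings was -0.41. Macrophage (-0.16, SE 0.043), neutrophil (-0.12, SE 0.055), lymphocyte (-0.096, SE 0.025), cholangiocyte (-0.085, SE 0.041) and hepatocyte (-0.079, SE 0.035) markers were lower too (SE between members), and by the bound used above, 50% of the matrix change, fewer of the last 4 cell types as the main cause are argued against, while fewer macrophages cannot be told apart, since their mean lies within 2 SE of that bound. Growth slowing with age may account for the change as a hypothesis, which stays untested along with lower matrix transcription per cell.

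Across genes, which are not independent, the 5-week slopes resembled the age difference, with a mean r of 0.489 over 6 slopes, from 0.199 for insulin and 0.388 for liver fat to 0.646 for body fat, and 0.0914 for the 12-week slopes. A chance order of the mice is argued against. Only 1 of 100 orders, the real one, gave a mean r as large, and the highest other was 0.204. Array batch as the whole cause is argued against, since within each of batches 1 to 4 alone 1 of 100 orders, the real one, gave a mean r as large, with 0.288, 0.215, 0.437 and 0.417 against highest others of 0.161, 0.123, 0.205 and 0.316, though the insulin slope in batch 2 alone was at -0.0556. With body weight in the fit the mean r was 0.218 and that of insulin -0.118, consistent with body weight as part of the cause, and the body weight slope itself called 2877 genes and had r = 0.62 with the age difference. A part played by array batch cannot be told apart, because the lowest batch value (0.215) lay below the pooled one and came from 43 mice, and whether heavier 5-week mice are further along the same course of disease or development stays open.

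In 8 arrays Eif2s3x and the mean of the other X-linked genes lay nearer to the other sex, of 8 by Eif2s3x and 74 by that mean: 3 females and 2 males at 5 weeks and 2 females and 1 male at 12 weeks. By 7 autosomal male-biased genes, 5 of the 8 (62.5%) lay on the side of the other sex, against 88 of 427 other arrays (20.6%). Noise of Eif2s3x alone is argued against by 100 orders of it within group and batch. Only the real one put as many against the label together with the other X-linked genes (highest other 4). By selection the 8 lay far from their labelled sex by Eif2s3x (4.36 to 6.94 SD). Wrong labels or exchanged samples cannot be told apart from a change shared by the X-linked genes, since the 8 arrays are few and the autosomal score misplaces many others. Swaps in pairs between males and females of an age as the whole cause are argued against by the 2 arrays left with no partner. No biological explanation, such as another number of X chromosomes, was tested.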

How the results depend on the processing

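All settings given here were chosen before the data were examined, except slopes per unit of a trait, the slope differences between ages of the traits other than glucose and the tests of traits within mice, whose 4 results are among those counted for traits. The number of arrays limits the precision, and signal over background is unknown. The 4 groups hold different mice with no shared replicate numbers, and no paired analysis was possible for expression because each mouse has 1 array. Among list results 3310 of 3867 kept direction and side of the threshold, 542 lost the call and 15 reversed. For named genes these were 4083 of 4230, 145 and 2. For traits they were 274 of 372, 86 and 5, and 7 gained a call. With quantile normalization, median centring, all probe sets, the mean of probe sets, dim genes left out, eBayes with trend and robust, or the arrays against the sex label left out, the counts of called genes of the 19 comparisons stayed within 1.5 times their values.

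With a correlation estimated per list, 62 of 201 list calls held. The counts of called genes changed as follows, and the cause was not tested. Without the batch term, the counts were at 5 weeks 2093 for glucose and 607 for insulin, and 1359 for the age difference of the glucose slope. With plate in place of batch, the count was at 5 weeks 675 for glucose. Without batch 1 they were at 5 weeks 936 for triglycerides, 1535 for cholesterol and 408 for liver fat, and 624 for the interaction and 218 for the sex difference of the glucose slope. Without batch 2 they were at 12 weeks 549 for glucose, 1810 for insulin, 1052 for triglycerides, 838 for cholesterol, 2077 for liver fat and 435 for body fat, at 5 weeks 144 for insulin, and 1307 for sex at 12 weeks, 736 for the interaction, 41 for the sex difference of the glucose slope and 275 for the age difference of the glucose slope. Without batch 3 they were at 12 weeks 1207 for cholesterol and 546 for body fat, at 5 weeks 721 for glucose, 35 for insulin, 268 for liver fat and 1015 for body fat, and 136 for the sex difference of the glucose slope and 586 for the age difference of the glucose slope. Without batch 4 they were at 12 weeks 379 for body fat, and at 5 weeks 405 for glucose, 104 for insulin and 420 for liver fat. The count for the sex difference of the glucose slope was 106 with unlogged glucose and 57 with normal scores. With slopes per log2 unit of the trait the differences between ages numbered 794 for insulin, against 1770 per SD, and 972 for liver fat, against 1692.

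With body weight in the fit the counts were at 12 weeks 1653 for body fat, at 5 weeks 406 for glucose, 178 for insulin, 522 for triglycerides, 716 for cholesterol and 1214 for body fat, and 339 for the age difference of the glucose slope. Reversed slopes at 5 weeks were, with glucose, -0.0034 for hepatocyte markers, and with triglycerides, 0.016 for immature liver genes and 0.013 for matrix genes. With cholesterol they were 0.042 for Igfbp1 and 0.0058 for immature liver genes. With body fat they were 0.059 for Igfbp1, 0.0065 for sterol synthesis, 0.0071 for immature liver genes and -0.0023 for hepatocyte markers. With insulin in the fit the count was at 12 weeks 949 for glucose, and the reversed value was 0.025 for fatty acid synthesis in glucose slope difference between ages. With glucose in the fit it was at 5 weeks 493 for insulin. In males only the counts were at 12 weeks 924 for glucose, 1653 for insulin, 1538 for triglycerides, 971 for cholesterol, 1714 for liver fat and 6 for body fat, and at 5 weeks 247 for glucose, 205 for insulin, 736 for triglycerides, 1562 for cholesterol, 278 for liver fat and 656 for body fat. Reversed values were 0.019 for male-biased genes in glucose slope at 12 weeks, -0.0060 for immediate early genes in body fat slope at 12 weeks, -0.0018 for oxidative phosphorylation in glucose slope at 5 weeks and 0.017 for fatty acid synthesis in glucose slope difference between ages. In females only the counts were at 12 weeks 1099 for glucose, 2203 for insulin, 1502 for triglycerides, 269 for cholesterol and 1788 for liver fat, at 5 weeks 217 for glucose, 2 for insulin, 669 for triglycerides, 1024 for cholesterol, 103 for liver fat and 850 for body fat, and 190 for the age difference of the glucose slope. The 12-week body fat count in females only was 1077, against 902 in all mice. Reversed values were 0.0077 for lipid droplet genes in glucose slope at 12 weeks, -0.00048 for xenobiotic metabolism in cholesterol slope at 5 weeks and -0.016 for sterol synthesis in glucose slope difference between ages. The cause of the reversals was not tested.

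Within a batch alone permutation tests called 0, 16, 7 and 2 of 44 trait correlations in batches 1 to 4, against 28 in all mice. At an unadjusted p under 0.05 there were 8, 18, 15 and 11. Reversed values of r were 0.110 for glucose with insulin in 5-week females (batch 2 alone), -0.0429 for insulin with triglycerides in 5-week males (batch 2 alone), 0.325 for glucose with insulin in 12-week males (batch 1 alone), 0.0242 for insulin with triglycerides in 12-week males (batch 1 alone) and 0.332 for week 5 glucose with insulin in 12-week males (batch 3 alone). The cause was not tested.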

Other observations

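The slope differences between ages of traits other than glucose, those per unit of a trait, and the reading of fatty acid synthesis with insulin in the fit as a test of a cause were chosen after the results were seen, though that fit was set before. Lepr windows other than 31 genes and cluster gaps under 4 SD were also added after. Fatty acid synthesis genes had a more positive insulin slope at 12 than at 5 weeks, 10 of 16 more positive (mean 0.18, adjusted p = 4.74e-16). Matrix genes did too, 12 of 16 more positive (mean 0.095, adjusted p = 4.4e-11), and so did sterol synthesis genes, 6 of 17 more positive (mean 0.11, adjusted p = 2.26e-06, adjusted p = 0.227 with an estimated correlation). Gluconeogenic genes went the other way, 4 of 12 more negative (mean -0.075, adjusted p = 0.000171, adjusted p = 0.0599 with an estimated correlation). With liver fat, fatty acid synthesis genes were more positive at 12 weeks, 10 of 16 more positive (mean 0.15, adjusted p = 2.08e-10), as were matrix genes, 9 of 16 more positive (mean 0.085, adjusted p = 2.01e-09), and interferon-stimulated genes, 6 of 14 more positive (mean 0.083, adjusted p = 6.79e-06, adjusted p = 0.222 with an estimated correlation).

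These slopes are per SD within an age, and insulin and liver fat were more spread at 12 weeks. An SD of insulin was 0.64 log2 in females and 0.70 in males at 5 weeks, against 1.09 and 1.21 at 12 weeks. For liver fat it was 0.17 and 0.19 against 0.25 and 0.30. Per log2 unit, the insulin slope differed between ages for 794 genes in place of 1770, and 760 were called both ways. The mean slope of fatty acid synthesis genes was then 0.060 at 5 and 0.19 at 12 weeks (adjusted p = 6.21e-09), and that of matrix genes -0.062 at 5 and 0.047 at 12 weeks (adjusted p = 9.5e-14). Sterol synthesis was at -0.029 at 5 and 0.076 at 12 weeks (adjusted p = 0.229 with an estimated correlation), and gluconeogenic genes at -0.039 at 5 and -0.088 at 12 weeks (adjusted p = 0.229 with an estimated correlation). The liver fat slope differed for 972 genes in place of 1692. With liver fat, fatty acid synthesis was at 0.18 at 5 and 0.67 at 12 weeks (adjusted p = 0.104 with an estimated correlation), matrix genes at -0.078 at 5 and 0.25 at 12 weeks (adjusted p = 0.0747 with an estimated correlation) and interferon-stimulated genes at -0.21 at 5 and 0.17 at 12 weeks (adjusted p = 0.144 with an estimated correlation).

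With triglycerides, the slopes of lipid droplet genes were more negative at 12 weeks, 8 of 11 more negative (mean -0.16, adjusted p = 4.04e-12), and so were those of fatty acid synthesis genes, 7 of 16 more negative (mean -0.15, adjusted p = 6.25e-08, adjusted p = 0.0532 with an estimated correlation). Sterol synthesis genes were more positive, 9 of 17 more positive and 1 more negative (mean 0.085, adjusted p = 5.59e-06, adjusted p = 0.224 with an estimated correlation), and so were xenobiotic metabolism genes, 13 of 28 more positive and 1 more negative (mean 0.071, adjusted p = 2.9e-06, adjusted p = 0.0532 with an estimated correlation). With cholesterol, the slopes of matrix genes were more positive, 10 of 16 more positive (mean 0.099, adjusted p = 2.77e-16), as were those of sterol synthesis, 13 of 17 more positive (mean 0.13, adjusted p = 3.63e-15), and fatty acid synthesis, 10 of 16 more positive (mean 0.13, adjusted p = 2.23e-09). With body fat the same held for matrix genes, 7 of 16 more positive (mean 0.078, adjusted p = 1.62e-14), cell cycle genes, 4 of 12 more positive (mean 0.073, adjusted p = 1.43e-08), and immature liver genes, 2 of 7 more positive (mean 0.050, adjusted p = 0.00205).

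Lower insulin in the more hyperglycaemic mice may account for their lower fatty acid synthesis transcripts, as a hypothesis. The mean glucose slope of the list went from -0.096 to 0.0044 with insulin in the fit (camera adjusted p = 0.985), while its insulin slope was 0.22 and 0.22 with glucose in the fit (adjusted p = 6.01e-19).

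In an F2 cross, linked inheritance could make neighbouring genes vary together. With neighbour order from GRCm38.p6, the mean squared residual correlation between mice was 0.0243 for adjacent genes, 0.0167 for genes 10 apart, 0.0155 for genes 50 apart and 0.0135 for genes on different chromosomes. At 10 genes apart it was above the value for different chromosomes on 18 of 19 chromosomes, which is consistent with linkage, and shared regulation of neighbouring genes was not tested. All mice carry the same mutation in Lepr, so genes around it were tested for weaker shared variation. Of 31-gene windows, 25.1% had a lower value than the window at Lepr, and the percentages were 27.0, 49.0, 24.3 and 41.9 for windows of 11, 21, 51 and 81 genes. With so many windows lower, this did not decide the question. A search for genes whose values fall into 3 clusters of at least 20 arrays found 0 at a gap of 4 SD, the gap set first. At gaps of 2, 2.5, 3 and 3.5 SD it found 71, 42, 13 and 4 genes, of which 30, 20, 7 and 1 had a chi-square p of at least 0.05 against a 1:2:1 ratio.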
